A study of Rattus norvegicus with 8 samples.

How the data were processed

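RNA was measured in rat sciatic nerve 15 days after chronic constriction injury (CCI, loose ligatures placed around the nerve as a model of neuropathic pain) or after a sham operation, in 4 libraries per group. Per the labels' protocols, RNA was extracted with a column kit and polyA libraries were made with a SMARTER mRNA-Seq kit. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries, part of which may be technical.

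The authors deposited a table of raw counts per gene and a table of FPKM values, both with 1 column per library. Per the submitters' processing notes, the tools were fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2, named without a role, and the genome build was Rnor_6.0. The annotation, the strand setting of the counting and any filter are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies are therefore uncertain, among them the haemoglobin genes, Tpi1 of the glycolysis list, the RT1 genes of the MHC class II list and the ribosomal protein genes. The deposited FPKM values equalled the count divided by gene length and by the summed count of the library, so they carry no correction for the makeup of the libraries. The deposited counts summed to between 42541217 and 54559292 per library over 22601 gene names. Of these names, 12 had been turned into dates by a spreadsheet and were kept without a guess at the gene, 17139 were current RefSeq symbols (assembly GRCr8, used for names and neighbours only) and 2080 were older symbols. No mitochondrially encoded gene was matched, so that list was not tested. Gene order in that assembly served only to find the neighbours of Fgf4, and no coordinates are given.

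The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, robust fit) on the deposited counts, CCI against sham without covariates, after filterByExpr and scaling by the trimmed mean of M-values (TMM). Of the 22601 genes, 15763 were tested, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p of single genes are from this test. Log2 fold changes are CCI against sham, with standard errors (SE) that are approximate, being the coefficient divided by the square root of F. Levels are TMM-normalised CPM (counts scaled to a common library total), given as mean ± SD with n = 4 per group. In a library 3 counts corresponded to between 0.0518 and 0.0771 CPM, the limit that a count of 0 allows for counting error only. Data were simulated with the mean levels of sham and the libraries' own depths, with 200 genes changed and a further list of genes raised 2-fold. With 15197 genes tested, the test recovered 44.8% of 67 genes changed 1.5-fold, 67.2% of 67 changed 2-fold and 90.9% of 66 changed 4-fold. There were 10 false calls. Far fewer genes changed there than the 68.4% called in the data, so these rates may not hold for the data.

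Before the data were examined, 30 gene lists were fixed from textbook knowledge: 12 primary lists, 5 secondary ones, 11 for other cell types and 2 for RNA quality. Each of the 29 lists with tested members was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 29 lists. Beside each called list stands the adjusted p with a correlation estimated from the data. Members were also counted with p-values adjusted over the list alone, and that count is given only where it differed. The genes to be named were fixed by rule: the 6 largest rises and 6 largest falls among called genes with at least 5 CPM on average and no overlap between groups. Also named were Fgf4, Hif1a, Slc2a1, Hk2, Pfkfb3, Pkm and Ldha, from each primary list the 2 members with the smallest p, and from each other list the 1 with the smallest p. Not every gene taken by this rule is reported here. Other genes named were chosen after their values were seen, to name the exceptions in a list or its most abundant members.

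Alternatives fixed before the data were examined were DESeq2's size factors, DESeq2 1.42.0, limma-voom with sample weights, no filter and a filter of at least 5 CPM in 4 libraries, the replicate number as a block, leaving out each library, a minimum log2 fold change of 1, limma on log2 FPKM, and other set tests. Chosen after seeing the data were scaling by library totals only, upper-quartile scaling, and leaving out CCI 2 and sham 2, the libraries richest in skeletal muscle RNA of their groups. No library was left out of the main test. Within groups, pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom between 28.8 and 78.6), so no pair was treated as 1 library. The lowest values were between sham 1 and 4 (28.8) and between sham 2 and 3 (31.1), against 52.6 to 78.6 for the other sham pairs. Principal component 3 (3.81% of the variance) divided the sham libraries in the same way. The labels do not say why.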

Results

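The series measured polyA RNA in the rat sciatic nerve 15 days after chronic constriction injury (CCI) or a sham operation, with 4 libraries in each group. Its title concerns FGF4, HIF-1α and glycolysis in neuropathic pain, and the comparison of CCI with sham nerve asks how these genes and the rest of the transcriptome differ in the injured nerve. Total counts were 54559292, 49074095, 42541217 and 43869402 in CCI 1 to 4 and 42654145, 45394077, 46942670 and 48573026 in sham 1 to 4. Libraries of 1 group correlated at r between 0.965 and 0.983 across genes, and libraries of different groups at r between 0.850 and 0.881. Genes are not independent replicates. The first principal component held 78.5% of the variance and separated the groups.

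The injured nerve differed from the sham nerve in most expressed genes. Of 15763 genes tested, 10788 (68.4%) changed, 5708 of them higher and 5080 lower in CCI, and 4774 changed at least 2-fold (2587 higher, 2187 lower). The 6 largest rises were in the matrix metalloproteinases Mmp12, Mmp13 and Mmp9, the matrix glycoprotein Tnn (tenascin N) and the chemokines Ccl9 and Cxcl6. Mmp13 rose from 0.174 ± 0.0724 to 93.3 ± 26.4 CPM and Mmp9 from 0.206 ± 0.121 to 94.4 ± 18.8 CPM (SD, n = 4). Tnn rose by 9.56 (SE 0.52), Ccl9 by 8.22 (SE 0.39) and Cxcl6 by 8.10 (SE 0.56) on the log2 scale. Mmp12 had 5 counts in all sham libraries together, and its ratio of CCI to sham was 1808 (95% counting interval 775 to 5569). The 6 largest falls were in Hif3a, a HIF alpha subunit, Hapln2, a link protein of the node of Ranvier, Cldn24, a claudin, Hrk, a BH3-only protein, Fmo2, a flavin monooxygenase, and Glyat. Hif3a went from 27.8 ± 8.94 to 0.681 ± 0.287 CPM and Fmo2 from 650 ± 345 to 23.0 ± 2.35 CPM. Hapln2 fell by 5.24 (SE 0.19), Cldn24 fell by 4.94 (SE 0.31), Hrk fell by 4.86 (SE 0.40) and Glyat fell by 4.61 (SE 0.30) on the log2 scale. All 12 had adjusted p of at most 3.00e-05 in edgeR's quasi-likelihood test. The share of calls that were higher in CCI was 52.9%, but 66.9% when libraries were scaled by their totals only and 68.2% in limma on log2(FPKM + 1). Scaling by totals moved the median log2 fold change of all tested genes from 0.05 to 0.27. The 10 most abundant genes of each library took 14.9% to 16.8% of the counts in sham libraries and 9.28% to 10.5% in CCI libraries.

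Fgf4, the growth factor of the series title, was 16.9-fold lower in CCI nerve, and Hif1a was 3.13-fold higher. Fgf4 had 51.7 ± 3.61 CPM in sham and 3.06 ± 0.319 CPM in CCI libraries (SD, n = 4; log2 fold change -4.08, SE 0.10; edgeR adjusted p = 2.07e-09). Hif1a went from 101 ± 8.43 to 316 ± 49.2 CPM (log2 fold change 1.65, SE 0.11; edgeR adjusted p = 3.66e-07). Among the glycolysis genes fixed beforehand, Ldha, which makes lactate from pyruvate, rose 2.05-fold (edgeR adjusted p = 4.40e-07), Pkm, the muscle-type pyruvate kinase, 1.69-fold (3.64e-05) and the hexokinase Hk2 1.61-fold (0.000101). The glucose transporter Slc2a1 went the other way, from 359 ± 49.5 to 117 ± 30.9 CPM (edgeR adjusted p = 4.51e-05). Pfkfb3 was at 92.5 ± 12.8 CPM in sham and 82.0 ± 7.84 CPM in CCI and did not pass (edgeR adjusted p = 0.155), with a log2 fold change of -0.17 (SE 0.10) that turned to 0.05 with library totals only. These are levels in whole nerve, in which macrophage genes rose (list median 2.45) and myelin genes fell (-3.29). For Hif1a and the glycolysis genes, a changed mix of cells was not tested and cannot be told apart from a change within cells.

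**Figure D1:**
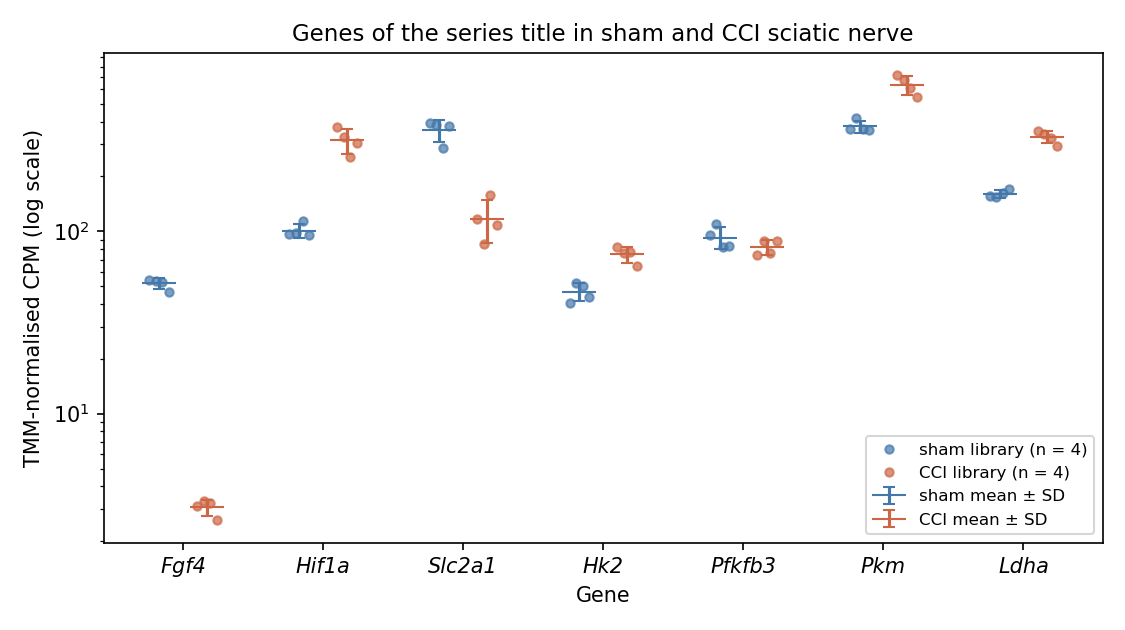
TMM-normalised CPM on a log scale for the 7 genes fixed beforehand from the series title, in sham (blue) and CCI (orange) sciatic nerve; points are libraries (n = 4 per group) and bars the mean ± SD. Fgf4 sits near 51.7 CPM in sham and 3.06 CPM in CCI, Hif1a, Hk2, Pkm and Ldha are higher in CCI, Slc2a1 is lower, and the groups overlap for Pfkfb3.

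Genes of glycolysis went both ways. Of 28 tested members, 14 rose and 7 fell (15 and 7 adjusted over the list alone), with a median log2 fold change of 0.72. Hk3, a hexokinase of myeloid cells, went from 0.522 ± 0.235 to 43.4 ± 3.64 CPM (edgeR adjusted p = 1.92e-08), and Aldoc, an aldolase isoform, from 103 ± 8.58 to 9.17 ± 1.03 CPM (edgeR adjusted p = 3.61e-09). The list as a whole did not pass camera (adjusted p = 0.321), while fry, which does not compare a list with other genes, gave an adjusted p of 0.00117. Its median was 0.41 without CCI 2, the library richest in skeletal muscle RNA, and 0.22 when only genes of at least 5 CPM in 4 libraries were kept. Without both CCI 2 and sham 2 it was 0.75, with 15 members higher and 7 lower.

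The HIF-1 pathway and hypoxia targets were divided in the same way, with 10 of 27 tested members higher and 10 lower. Hif1a itself was among the higher ones, while Ndrg1, a hypoxia-induced gene that is also abundant in myelinating Schwann cells, went from 3458 ± 421 to 501 ± 71.8 CPM (edgeR adjusted p = 2.59e-08) and Egln1, a prolyl hydroxylase that marks HIF-1α for degradation, from 79.9 ± 2.48 to 40.1 ± 2.82 CPM (edgeR adjusted p = 2.81e-07). The median of the list (-0.10) and the direction of camera (down, adjusted p = 0.707) differed in sign from its mean of 0.28. With library totals only the median was 0.13, with 12 members higher and 6 lower, but relative to all tested genes it was -0.15 with TMM and -0.14 with totals. Without CCI 2 and sham 2, the libraries richest in muscle RNA of their groups, 6 members were higher and 10 lower.

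Genes of FGF signalling were mostly lower. Of 33 tested members, 18 fell and 7 rose, with a median of -0.47 (camera adjusted p = 0.0237, and adjusted p = 0.136 with an estimated correlation). Besides Fgf4, the strongest evidence was for Fgf1, which went from 470 ± 42.3 to 49.3 ± 7.36 CPM (edgeR adjusted p = 7.34e-09). Of the receptors, Fgfr1, Fgfr2 and Fgfr3 were among those that fell and Fgfr4 among those that rose. The call of the list was lost without CCI 2 (camera adjusted p = 0.0525) and without CCI 2 and sham 2 (0.0554), with a median of -0.47 in both. The median of the skeletal muscle list went from 2.28 to 0.58 without CCI 2, and to 3.82 without CCI 2 and sham 2.

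Myelin genes and the genes of cholesterol synthesis fell together. Of 24 tested genes of myelin and the myelinating Schwann cell, the glia that wrap axons, 23 fell and 0 rose (median -3.29; camera adjusted p = 8.42e-30, and adjusted p = 0.0814 with an estimated correlation). Fa2h, which makes the hydroxylated lipids of myelin, fell by 3.96 on the log2 scale (SE 0.12; edgeR adjusted p = 3.80e-09). Ncmap, a myelin membrane protein, went from 571 ± 51.1 to 59.4 ± 6.32 CPM (3.85e-09). The abundant myelin gene Mbp fell by 3.59 on the log2 scale (SE 0.11). The 1 member not past the threshold was Pou3f1, a transcription factor of Schwann cells (log2 fold change -0.32, SE 0.17). All 24 cholesterol synthesis genes fell (median -2.20; camera adjusted p = 2.91e-26, and adjusted p = 0.0886 with an estimated correlation), among them Sc5d, from 465 ± 46.3 to 46.0 ± 4.71 CPM, and Insig1, a regulator of the pathway, from 164 ± 10.3 to 40.1 ± 1.52 CPM.

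Genes of the repair Schwann cell, the state that Schwann cells take on after injury, were mostly higher. Of 22 tested members, 13 rose and 2 fell (median 0.87; camera adjusted p = 0.0204, and adjusted p = 0.382 with an estimated correlation). Tnfrsf12a, the TWEAK receptor, went from 4.87 ± 0.762 to 25.3 ± 1.21 CPM (edgeR adjusted p = 4.35e-08), and the transcription factor Runx2 from 10.1 ± 1.52 to 83.8 ± 17.0 CPM (2.08e-07). The 2 that fell were L1cam, an adhesion molecule, and Olig1. With library totals only the list no longer passed (median 1.10; camera adjusted p = 0.0564), though its median relative to all tested genes was 0.82 with either scaling.

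Macrophage genes rose, with lysosomal and inflammatory genes. Of 25 tested macrophage and monocyte genes, 22 rose and 1 fell (median 2.45; camera adjusted p = 1.02e-18, and adjusted p = 0.0814 with an estimated correlation), led by the pattern receptor Clec7a, from 4.10 ± 0.780 to 88.1 ± 6.59 CPM (edgeR adjusted p = 3.61e-09), and Adgre1, which encodes F4/80, from 16.9 ± 2.01 to 119 ± 7.78 CPM (5.27e-09). The 1 that fell was Spp1, osteopontin, from 3714 ± 1937 to 1648 ± 256 CPM (edgeR adjusted p = 0.0240), with 5345 and 5422 CPM in sham 2 and 3 and 2283 and 1808 CPM in sham 1 and 4, of which sham 4 lay within the range of the CCI libraries (1363 to 1967 CPM). The call of Spp1 was lost with library totals only (edgeR adjusted p = 0.0512), without CCI 2 and sham 2 (0.115), and without CCI 2 (0.0538), CCI 4 (0.0632), sham 2 (0.0619) or sham 3 (0.0547). Of 25 lysosome and lipid uptake genes, 17 rose and 3 fell (4 fell adjusted over the list alone; median 1.14; camera adjusted p = 9.35e-09, and adjusted p = 0.0648 with an estimated correlation), among them the cathepsin Ctsz, from 26.1 ± 2.20 to 286 ± 33.8 CPM, and the acid lipase Lipa, from 26.7 ± 2.93 to 160 ± 11.1 CPM. Of 28 cytokines and chemokines, 22 rose and 2 fell (median 2.71; camera adjusted p = 1.52e-06, and adjusted p = 0.0648 with an estimated correlation). Il1b, a pro-inflammatory cytokine, went from 0.806 ± 0.241 to 33.4 ± 4.56 CPM and Ccl2, which attracts monocytes, from 4.11 ± 0.540 to 57.6 ± 11.2 CPM. The 2 that fell were Il33 and Il34, of which Il33 did not pass with library totals only (edgeR adjusted p = 0.266) or without CCI 2 and sham 2 (0.101).

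Matrix genes and cell cycle genes were higher in the injured nerve. Of 34 tested genes of extracellular matrix and fibrosis, 29 rose and 2 fell (median 1.12; camera adjusted p = 3.59e-09, and adjusted p = 0.0886 with an estimated correlation). Thbs2, a thrombospondin, went from 201 ± 18.9 to 1019 ± 48.7 CPM and Loxl1, which crosslinks elastin, from 34.3 ± 5.07 to 184 ± 6.79 CPM. The 2 that fell were the proteoglycan Dcn and Sparc, the latter not with library totals only (edgeR adjusted p = 0.127), and the 3 not past the threshold were the fibrillar collagens Col1a1, Col1a2 and Col3a1. All 30 cell cycle genes rose (median 3.91; camera adjusted p = 6.76e-32, and adjusted p = 0.0648 with an estimated correlation), among them the mitotic kinesin Kif11, from 2.26 ± 0.221 to 41.4 ± 2.08 CPM (edgeR adjusted p = 2.07e-09), and the replication helicase subunit Mcm3, from 4.61 ± 0.395 to 36.8 ± 2.43 CPM (3.85e-09).

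Ion channel and peptide genes of nociception went both ways, and more fell than rose. Of 21 tested members, 11 fell and 5 rose (median -0.59), and the list did not pass camera (adjusted p = 0.101). The potassium channel genes Kcna1, from 394 ± 56.7 to 29.6 ± 7.45 CPM (edgeR adjusted p = 1.54e-07), and Kcna2, which fell by 3.16 on the log2 scale (SE 0.17; 1.90e-07), had the smallest p. Which cells of the nerve held the transcripts of this list was not tested. The 5 that rose were P2rx4, an ATP receptor, the calcium channel genes Cacna1b and Cacna2d1, the peptide gene Gal and Trpm8. The list passed with a filter of at least 5 CPM in 4 libraries (median -1.17; camera adjusted p = 0.0181), with the replicate block (0.0264), with library totals only (0.0426) and by fry (6.28e-06).

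**Figure D2:**
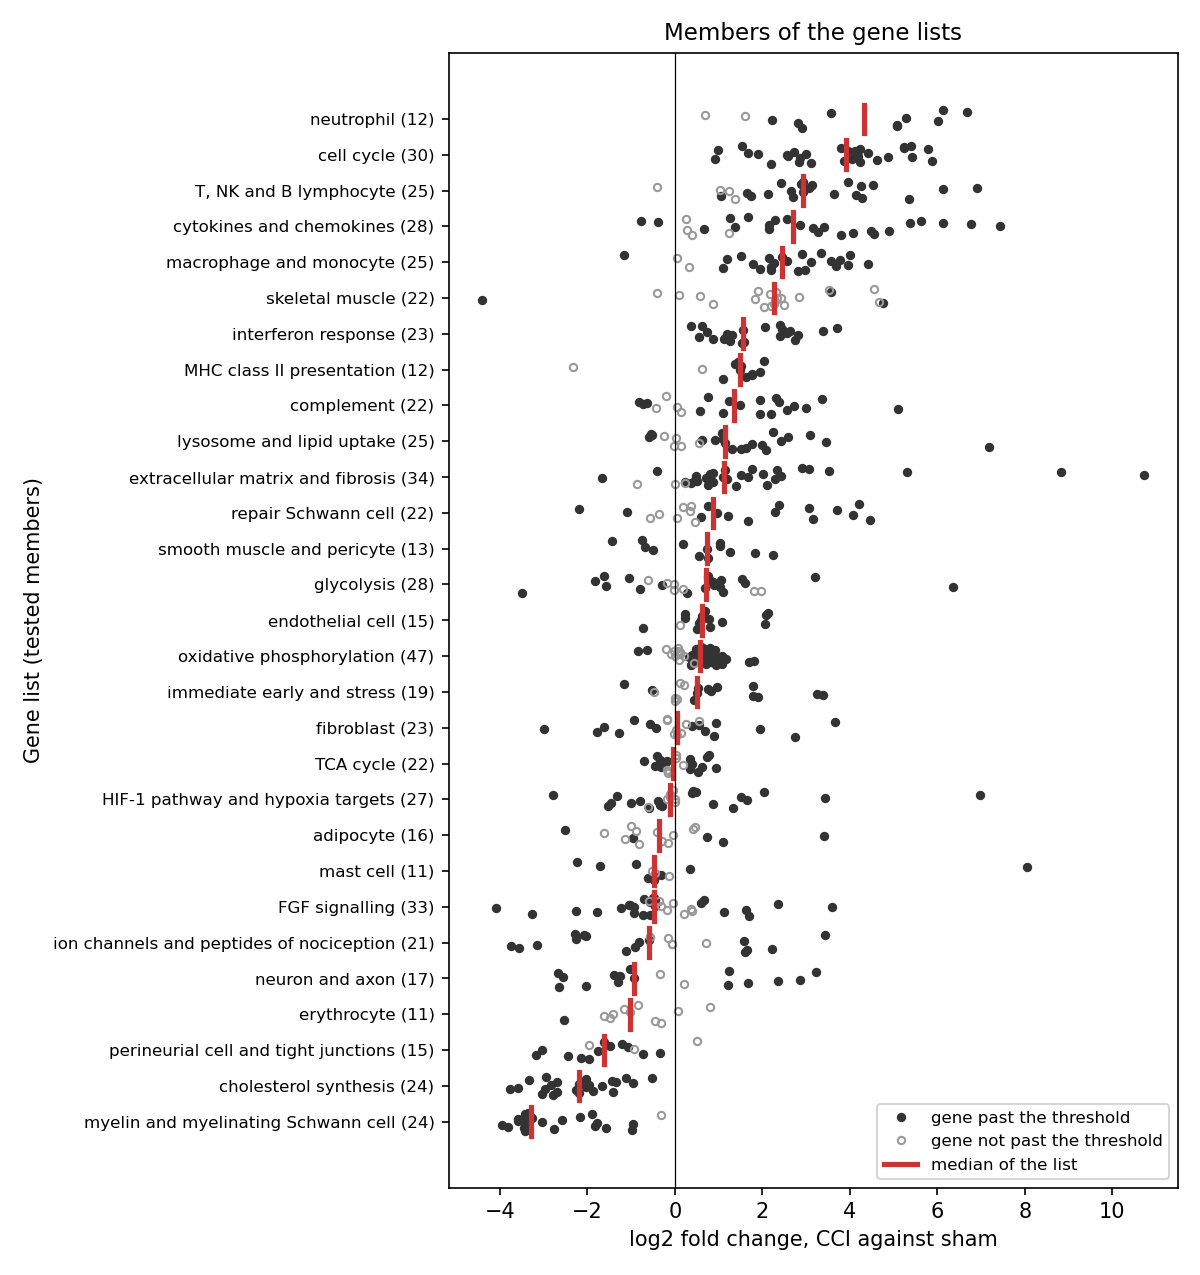
Log2 fold change of CCI against sham for each tested member of the 29 gene lists, ordered by median (red bar), with the number of tested members in brackets; filled points passed an edgeR adjusted p of 0.05 and open points did not. Myelin (median -3.29) and cholesterol synthesis (-2.20) lie lowest and neutrophil (4.32) and cell cycle genes (3.91) highest, while glycolysis and HIF-1 genes lie on both sides of 0.

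Genes of mitochondrial respiration and of innate and adaptive immunity were described by 5 secondary lists. Of 47 oxidative phosphorylation genes, 34 rose and 2 fell, Ndufs4 and Ndufs7 (median 0.57; camera adjusted p = 0.00108, and adjusted p = 0.635 with an estimated correlation), with Cox5a, a subunit of cytochrome c oxidase, going from 11.4 ± 0.883 to 39.8 ± 4.35 CPM. The tested genes of this list are short, with a median length of 853 bp against 3020 bp for all, and shorter genes had higher log2 fold changes across all genes. Of 22 tested genes of the TCA cycle, 8 rose and 8 fell (median -0.04, unlike in sign to the mean of 0.08 and to camera, direction up, adjusted p = 0.865), among the latter Pdha1, a subunit of pyruvate dehydrogenase, from 108 ± 5.39 to 66.5 ± 3.63 CPM. With library totals only the median was 0.18, 11 were higher and 3 lower, and Pdhb and Ogdh did not pass, with log2 fold changes of 0.05 and 0.01 in place of -0.17 and -0.22, while relative to all tested genes the median was -0.09 with either scaling. Pdhb also lost its call without CCI 4 or without sham 1, 3 or 4 (edgeR adjusted p = 0.0561 to 0.0865). Complement genes rose in 15 of 22 cases and fell in 3, Cd59, Cd55 and C7 (median 1.36; camera adjusted p = 2.71e-05, and adjusted p = 0.275 with an estimated correlation), with C2 rising by 2.57 (SE 0.10). The call of C7 was lost with library totals only (edgeR adjusted p = 0.121), without CCI 2 and sham 2 (0.175), and without CCI 1, 2 or 3 or sham 2 or 3 (0.0515 to 0.0983). All 23 interferon response genes rose (median 1.56; camera adjusted p = 0.000653, and adjusted p = 0.613 with an estimated correlation), with Gbp2 going from 26.1 ± 4.35 to 176 ± 33.8 CPM. Without CCI 2 and sham 2, 20 of them passed, but not Mx2 (edgeR adjusted p = 0.172), Rsad2 (0.0802) or Stat2 (0.0687). The call of Mx2 was also lost without any 1 library except CCI 4 (edgeR adjusted p = 0.0562 to 0.112). That of Stat2 was lost without CCI 1, 2 or 3 or sham 1, 3 or 4 (0.0539 to 0.110). Of 12 genes of MHC class II presentation, 10 rose and 0 fell (median 1.49; camera adjusted p = 0.00222, and adjusted p = 0.351 with an estimated correlation), with Cd83, a marker of activated antigen-presenting cells, rising by 1.78 (SE 0.13).

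Markers of other cell types moved apart from each other. Lymphocyte genes rose in 21 of 25 cases and fell in 0 (median 2.92; camera adjusted p = 2.05e-05, and adjusted p = 0.102 with an estimated correlation), with the chemokine receptor Ccr7 going from 0.175 ± 0.0317 to 7.32 ± 0.496 CPM. Neutrophil genes rose in 10 of 12 cases (11 adjusted over the list alone; median 4.32; camera adjusted p = 0.00107, and adjusted p = 0.280 with an estimated correlation), with Fcnb, a ficolin, going from 0.259 ± 0.127 to 16.9 ± 4.71 CPM. Endothelial genes rose in 13 of 15 cases and fell in 1, Cldn5 (median 0.63; camera adjusted p = 0.00108, and adjusted p = 0.289 with an estimated correlation), with the receptor Tie1 rising by 2.14 (SE 0.07). Genes of perineurial cells and tight junctions, which form the barrier around nerve bundles, fell in 12 of 15 cases and rose in 0 (13 and 1 adjusted over the list alone; median -1.61; camera adjusted p = 1.52e-06, and adjusted p = 0.0886 with an estimated correlation). In this list 9 fell and 0 rose without CCI 2 and sham 2 (median -1.33), and 10 fell and 1 rose with library totals only (median -1.38).

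The other lists did not pass camera. Mast cell genes fell in 6 of 11 cases and rose in 2 (median -0.47 and camera direction down, adjusted p = 0.327, unlike in sign to the mean of 0.10, and fry adjusted p = 0.0127). The 2 that rose were Kit and Mcpt2, a mast cell protease with 1 count in all sham libraries together and a ratio of CCI to sham of 383 (95% counting interval 68.8 to 15133). Of 13 smooth muscle and pericyte genes 9 rose and 4 fell, Smtn, Tagln, Myh11 and Lmod1 (median 0.73; camera adjusted p = 0.321, and fry adjusted p = 0.000298), of which Lmod1 did not pass with library totals only (edgeR adjusted p = 0.165) or without CCI 2 and sham 2 (0.106). Of 23 fibroblast genes 8 rose and 7 fell, among them Etv1, which fell by 1.79 on the log2 scale (SE 0.10). The median and mean of this list were 0.04 and 0.13, unlike in sign to camera (direction down, adjusted p = 0.782). Neuronal and axonal genes, whose mRNA can lie in axons, rose in 6 and fell in 9 of 17 cases (median -0.94; camera adjusted p = 0.642). Uchl1 fell by 1.02 on the log2 scale (SE 0.06). With a filter of at least 5 CPM in 4 libraries the median was 1.41. Of 16 adipocyte genes 3 rose, Fabp4, Aqp7 and Lep, and 2 fell, Pnpla2 and Dgat2 (1 and 2 adjusted over the list alone; median -0.35; camera adjusted p = 0.642). The call of Fabp4 was lost with DESeq2 size factors (edgeR adjusted p = 0.0512), without CCI 2 and sham 2 (0.137) and without any 1 library except sham 4 (0.0727 to 0.114), and that of Aqp7 without CCI 2 and sham 2 (0.106) and without any 1 library except CCI 3 and sham 4 (0.0505 to 0.0985). The median of this list was 0.10 without sham 4. Of 11 erythrocyte genes 1 fell, Epb42, by 2.52 on the log2 scale (SE 0.35; list median -1.02; camera adjusted p = 0.507 for the list). Of 19 immediate early and stress genes, which respond to handling of tissue as well as to injury, 11 rose, Jun among them with a log2 fold change of 0.96 (SE 0.11), and 2 fell, Nr4a1 and Hsph1 (median 0.51; camera adjusted p = 0.210, and fry adjusted p = 0.0127).

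Skeletal muscle transcripts differed widely between libraries of the same group. Of 22 tested muscle genes 2 rose, Mb and Tnnt1, and 1 fell, the slow myosin gene Myh7, from 29.0 ± 9.11 to 1.37 ± 0.443 CPM (1 and 1 adjusted over the list alone; camera adjusted p = 0.782). The call of Mb was lost without CCI 2 and sham 2 (edgeR adjusted p = 0.0949) and without any 1 library except CCI 1 (0.0573 to 0.101). Atp2a1, the calcium pump of fast fibres, was at 365 CPM in CCI 2, 72.6 in CCI 3, 36.1 in CCI 4 and 0.622 in CCI 1, and at 79.3 CPM in sham 2 against 0.437, 2.28 and 1.52 CPM in sham 1, 3 and 4. The median log2 fold change of the list was 2.28, and it was 0.58 without CCI 2, 5.29 without sham 2 and 3.82 without both, with 5 members higher and 2 lower. Haemoglobin RNA also differed within groups, with Hba1 at 4016 and 4458 CPM in sham 1 and 4 and 592 and 874 CPM in sham 2 and 3.

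**Figure D3:**
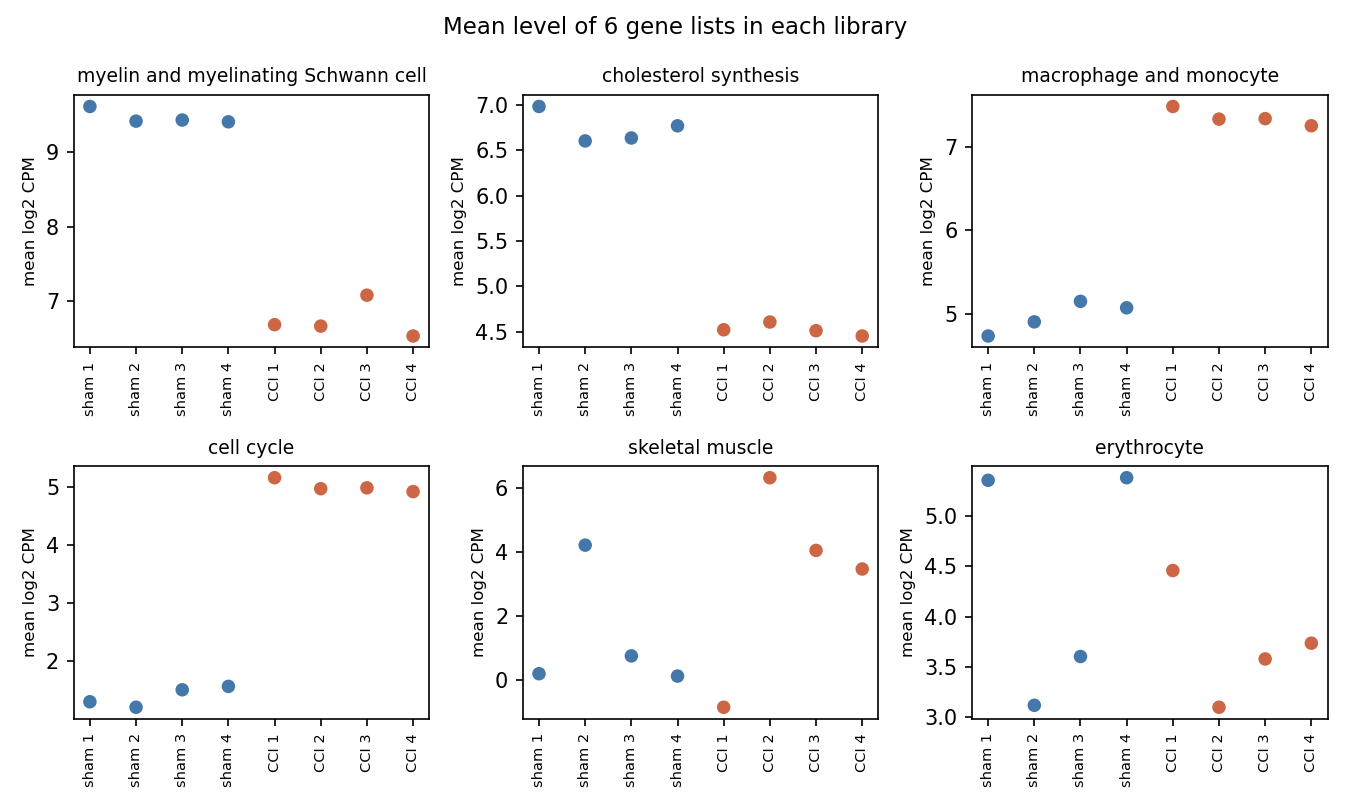
Mean log2 CPM of the tested members of 6 gene lists in each sham (blue) and CCI (orange) library; each point is 1 library and each panel has its own scale. Myelin and cholesterol synthesis are lower and macrophage and cell cycle genes higher in every CCI library than in every sham library, while skeletal muscle is highest in CCI 2 (6.31) and erythrocyte genes in sham 4 (5.38) and sham 1 (5.35).

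The labels name no batch. The exceptions named in each list were chosen after their values were seen. The list tests depended on the assumed correlation between genes: with a preset correlation 17 of 29 lists passed, with an estimated one 0, and by fry 22.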

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

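The tests of Schwann lineage genes, of the myelin list and of muscle RNA below were chosen only after the result was seen. In each group of 4 libraries the highest and lowest library were compared with the rest by Dixon's ratio, over 176 groups of values, and 15 stood apart where chance gives about 1 in 20 groups, or 8.8.

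Of the 7 genes fixed beforehand from the series title, 4 had a sham library apart from the other 3. Fgf4 was at 46.4 CPM in sham 4 against 53.0 to 54.1, Hif1a at 113 CPM in sham 3 against 95.5 to 97.4, Slc2a1 at 285 CPM in sham 3 against 378 to 392, and Pkm at 418 CPM in sham 2 against 360 to 364. These gaps were small beside the differences between CCI and sham. Among other named genes, sham 2 stood apart for Pdha1 (116 CPM against a median of 105), Smtn (290.0 against 274), Fcnb (0.0706 against 0.309), Mmp12 (0.0471 against 0.0232, a matter of 2 counts against 1) and Mcpt2 (0.0235 CPM, or 1 count, against 0). Sham 1 stood apart for Tnn (1.08 CPM against 0.325) and Jun (89.4 against 116), and CCI 3 for Ccl9 (68.4 CPM against 37.6). Of the list levels, given as mean log2 CPM, myelin was at 9.61 in sham 1 against 9.41 to 9.43, and neuronal genes at 1.97 in sham 2 against 2.24 to 2.28.

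The skeletal muscle list was at 4.21 mean log2 CPM in sham 2 against 0.13 to 0.76 in the other sham libraries, and at 6.31, 4.04 and 3.46 in CCI 2, 3 and 4 against -0.84 in CCI 1. An effect of CCI common to its libraries stays open: 3 of the 4 CCI libraries lay at or below sham 2, but only 1, CCI 1, at or below the next highest sham library, so that the overlap rests on single libraries. Adjacent muscle in some samples may account for the pattern: over the 4 libraries with more than 10 CPM of Atp2a1, the SD of the log2 ratio of 10 muscle genes to it had a median of 0.288, with Ttn (0.667) and Neb (0.757) the least constant, while Atp2a1 itself spanned 3.34 on the log2 scale. Ttn and Neb were lower relative to Atp2a1 in sham 2 than in CCI 2, 3 and 4. Atp2a1 was at 79.3 CPM in sham 2 and 72.6 in CCI 3, but Ttn at 342 and 618 CPM and Neb at 72.7 and 173 CPM. Sham 2 was the only sham library in this comparison, so a difference between groups in these ratios was not tested. Acta1, the most abundant of the 10 muscle genes beside Ttn, was at 833 CPM in CCI 2 and 251 CPM in sham 2. No other source of muscle RNA was tested.

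For the fall of Fgf4, dilution of Schwann cell RNA by other cells alone would lower it as much as 6 Schwann lineage genes, among them Sox10 and S100b. Their log2 fold changes were unequal, from -2.51 to -0.45 (the latter not past the threshold), and Fgf4 at -4.08 lay -2.08 from their median and below each of them, while per library the difference in log2(Fgf4 / their median level) was -2.56 (SE 0.18, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give). Reads of neighbouring genes are argued against by levels: the nearest genes in the table, Fgf3 and Fgf19, were at 0.243 and 0 CPM in sham against 51.7 for Fgf4, and the nearest tested ones, Ano1 and Ccnd1, had log2 fold changes of -0.62 and 2.38. Loss of the myelinating Schwann cell programme may contribute and stays open: Fgf4 lay -1.33 SD from the mean of the myelin list (mean -2.72, SD 1.02), a test that many falling genes would pass, and it lay below each of the 24 tested members, the lowest at -3.96. Overlap with an antisense transcript stays open, since the strand setting of the counts is not given.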

How the results depend on the processing

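Scaling by library totals, upper-quartile scaling and leaving out CCI 2 and sham 2 were chosen only after the data were seen. For the genes named by rule, most of them picked for large changes or small p, 1000 recomputed values kept direction and side of the threshold and 1 reversed. That was Pfkfb3, with a log2 fold change of 0.051 with library totals. Of all changed genes, 75.8% kept their call in limma on log2(FPKM + 1) and 87.0% with library totals only. The share was 89.0% without CCI 2 and sham 2 and 99.3% with upper-quartile scaling. Of the list values 519 kept both, 20 lost their call, 8 gained one and 4 reversed. Leaving out each library gave 10217 to 10540 changed genes and 16 to 17 called lists, and 6 of the 7 genes fixed from the series title passed under each of 17 alternatives.

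With an estimated correlation 0 lists were called by camera, at unchanged medians of -0.47 (FGF signalling), -3.29 (myelin), -2.20 (cholesterol synthesis), 0.87 (repair Schwann cell), 2.45 (macrophage), 1.14 (lysosome), 2.71 (cytokines), 1.12 (matrix) and 3.91 (cell cycle), since only the assumed correlation differs. By fry, which asks another question, glycolysis (0.72), nociception (-0.59), mast cell (-0.47), smooth muscle (0.73) and immediate early genes (0.51) gained a call. Nociception also gained one at -1.17 with at least 5 CPM in 4 libraries, at -0.61 with the replicate block and at -0.36 with library totals. FGF signalling ranged from -0.53 to -0.44 with single libraries left out, losing its call without CCI 2, and lost it at -0.47 without CCI 2 and sham 2, which leaves muscle RNA in CCI 3 and 4 only. Library totals move all genes alike, so the medians of the HIF-1 list (0.13) and the TCA cycle (0.18) changed sign without moving relative to all tested genes. The call of repair Schwann cell genes (1.10) ended with library totals. The neuronal list reversed to 1.41 with the stricter filter, which tests fewer members, and the adipocyte list ranged from -0.62 to 0.10 with single libraries left out, reversing without sham 4. The cause of these changes was not tested further.

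A minimum log2 fold change of 1 left 4774 genes (2587 higher, 2187 lower), and limma on FPKM called 3132 genes lower with a pseudocount of 1 and 3126 with 0.1, against 5080. These fits differ from the main test in the scaling, the test and the genes tested (12852), and a pseudocount of 1 without a filter gave 3788 changed genes, lower in CCI. DESeq2 called 11325 genes, limma-voom 10904, the stricter filter 8855 and the fit without CCI 2 and sham 2 9769. Whether the replicate numbers pair the libraries is not given in the labels. Deviations from the group means correlated across genes at 0.12, 0.29, -0.02 and 0.03 in same-numbered libraries, against -0.32 to 0.13 in the others. Genes are not independent replicates, so these values cannot decide whether the libraries are paired. The replicate block called 10505 genes and 18 lists and changed no other call among the lists. Depth limits the low genes most, such as Mmp12 and Mcpt2, with 5 and 1 counts in sham.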

Other observations

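The 7 lists described here were chosen only after the changed genes were seen, as was using 5 length binnings instead of 1.

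Transcripts of fatty acid synthesis genes were mostly lower in CCI nerve. Of 15 tested genes of fatty acid synthesis 12 fell and 0 rose (median -1.07; camera adjusted p = 1.82e-05, and adjusted p = 0.125 with an estimated correlation), among them Scd2, a desaturase, from 11020 ± 711 to 2136 ± 575 CPM, and Fasn, fatty acid synthase, from 713 ± 86.6 to 208 ± 30.5 CPM (SD, n = 4). Of 15 genes of nodes of Ranvier and paranodes 12 fell and 1 rose, Cntn1 (median -1.08; camera adjusted p = 0.00181, and adjusted p = 0.125 with an estimated correlation), with Nfasc, neurofascin, going from 765 ± 74.7 to 66.4 ± 15.2 CPM. With library totals only, 9 node genes fell and 1 rose (median -0.85), and 10 fatty acid synthesis genes fell and 1 rose (median -0.84). The genes of the node list are long (median 7581 bp), and length was not tested for it. Of 16 circadian clock genes 11 fell and 1 rose, Bhlhe41 (median -0.93; camera adjusted p = 0.00183, and adjusted p = 0.240 with an estimated correlation). The labels used here give no hour of collection.

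All 29 tested cytosolic ribosomal protein genes rose (median 0.84; camera adjusted p = 2.17e-06, and adjusted p = 0.344 with an estimated correlation), with reads of pseudogenes uncertain. These genes are short (median 765 bp), shorter genes had higher log2 fold changes in these data, and length was not tested for this list. The count includes Rps6 and Rps9, at under 1 CPM in both groups. Of 15 genes of iron handling 10 rose and 2 fell, Fth1 and Hamp (median 0.64; camera adjusted p = 0.0605), and the ferritin subunits moved apart: Ftl1 went from 775 ± 46.9 to 1746 ± 150 CPM and Fth1 from 5243 ± 262 to 2346 ± 103 CPM. Of 18 bone and cartilage genes 3 rose and 8 fell (median -0.66; camera adjusted p = 0.0966), with Col2a1 going from 224 ± 32.4 to 17.3 ± 4.76 CPM. In this list 3 rose and 5 fell with library totals only (median -0.43), and likewise without CCI 2 and sham 2 (median -0.56).

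Of the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 split, gave as many as 10788 changed genes. The highest of the others gave 0. A mixed split puts CCI and sham libraries into 1 group, where their large difference counts as spread, so 0 calls says little. Since 1 of 35 is the smallest share possible and the libraries may not come from separate animals, chance is not excluded.

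The rise of oxidative phosphorylation genes was weighed against gene length and scaling. The test of scaling decides nothing, since a scaling moves all genes alike: the list's median lay 0.53 above that of all tested genes with TMM and 0.52 with library totals. Gene length stays open too: the list's genes are short (median 853 bp against 3020 bp), and the median log2 fold change of all genes went from 0.33 in the shortest of 5 length classes to -0.17 in the longest. The list's median lay at percentile 97.7 among 10000 random lists matched on length and expression in the first matching, just past the bound set for it, but between 95.8 and 99.3 over 5 binnings with 2 seeds each. The 3 coarser binnings were past the bound and those with 30 and 40 length bins were not, so that length may account for it and cannot be told apart from a change of the list.

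A hypothesis from the fall of Hif3a, Klf15 and Fmo2 was that genes induced by glucocorticoids were lower as a class. The median log2 fold change of 10 other such genes was -1.48, with 5 lower and 0 higher (camera adjusted p = 0.0251, and adjusted p = 0.407 with an estimated correlation). All 10 were higher in sham 2 and 3 than in sham 1 and 4, such as Mt2A at 113 and 47.6 against 9.40 and 8.98 CPM and Fkbp5 at 232 and 183 against 137 and 82.7 CPM, and so was Fmo2, at 1067 and 797 against 401 and 336 CPM. The hypothesis stays open: with an estimated correlation 0 of the 29 lists of the report passed either, so that test could not decide, and the genes differed within sham as above.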
